A study of Mus musculus with 5 samples.

How the data were processed

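Whole cerebella of mice at postnatal day 14 were profiled by bulk RNA-seq in 2 control and 3 Yy1 cKO libraries. Per the labels, RNA was extracted with TRIzol and depleted of ribosomal RNA, the libraries were strand-specific, and paired-end reads of 150 bp were sequenced. Per the submitters' processing notes the tools were FastQC 0.11.8, Trimmomatic 0.39, STAR 2.7.1a, featureCounts and DESeq2 1.26.0, with the genome build GRCm38. The order and settings of these steps, including the strand setting of the counting and the treatment of reads with several matches, are not given in the sources used here. Values of genes with near-identical copies or an overlapping antisense partner are therefore uncertain. The first deposited table holds raw read counts of 55421 genes, as whole numbers, with totals of 17424860 to 20305705 per library. The second deposited table holds a normalized signal, which in every library equals the raw count divided by 1 constant. These constants, 0.969 to 1.07, equal the size factors that DESeq2 gives on the raw counts, and the table keeps the 24859 genes with at least 11 counts in total.

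Gene symbols and positions came from GENCODE M21 on GRCm38. Of the gene identifiers 54587 matched with their version, 567 matched without it, and 267 had no match. Groups were taken from the sample titles. Library pairs were compared before averaging. Over genes with at least 50 counts in the pair, chi-square per gene was 3.5 to 16.7 within groups and 34.1 to 41.5 between groups, so no library was a copy of another. The replicate numbers were checked for pairing, with the result in the closing section.

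The main test was the edgeR 4.0.16 quasi-likelihood test on raw counts in R 4.3.3, with TMM scaling, the filterByExpr filter, robust dispersion, no covariate and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. It kept 20388 genes, and the common biological coefficient of variation was 10.5%. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. Levels are TMM-scaled CPM, given as mean ± SD. The test, the alternatives, 37 gene lists and the rule for named genes were written before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with p adjusted over the 36 lists that had measured members; the Hox gene list had too few. Camera was repeated with an estimated correlation, and fry was run beside it. Named genes were Yy1 and Wnt10b and, among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups, the 10 with the largest change and the 5 with the smallest p in each direction, then up to 4 members of each list by p. Of the last the text gives those that describe a list best. Some genes that the rule picks are not reported here.

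The main test and the lists departed from that plan in 2 ways, and other choices made after results were seen are stated where they occur. Wnt10b did not pass the filter, so its value comes from the same fit with Wnt10b added back, a choice made after this was seen. A further 4 lists (growth network, angiogenic endothelium, fibroblast matrix and clock genes) were written after the leading genes had been seen, adjusted among themselves and used in the closing section.

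The test was checked on simulated counts with the means and totals of these libraries and 200 genes changed by known folds, under a pair of dispersion models. With dispersions drawn around the fitted trend it recovered 22.4% of 1.5-fold, 55.2% of 2-fold and 87.9% of 4-fold changes among 20388 genes, and 9 of 119 calls were false. With the dispersion estimated for each gene it recovered 41.8%, 70.1% and 93.9%, and 20 of 157 calls were false. The share of false calls was thus above the nominal 5% under both models. Only 200 genes were changed in the simulation, while 4762 were called in the data. With fewer true changes the adjustment demands a smaller p, so recovery and false shares in the data may differ from these. With no gene changed there were 0 and 1 calls, and camera called 0 lists. The simulated genes were drawn independently, so this does not check list calls where the genes of a list vary together. The second model was the first one run, and the trend model was added after its false share had been seen.

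The alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, edgeR without robust dispersion, limma-trend on log2 of the deposited normalized signal plus a pseudocount of 1, the replicate number as a block, log2 CPM of Xist as a covariate, removal of sex-linked, mitochondrial and haemoglobin genes, other thresholds, and leaving out each library in turn. A correction for GC content and exon length was added after the data were seen. Where 1 control is left, its spread is assumed to be that of the Yy1 cKO libraries. A change of sign was counted as a reversal only where either value passed the threshold.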

Results

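Bulk RNA-seq was carried out on whole cerebella of mice at postnatal day 14, when the granule cell precursors of the external layer are finishing their divisions and Purkinje cells are extending their dendrites. The 3 Yy1 cKO libraries came from mice with Pcp2-Cre and 2 floxed copies of Yy1. In these animals the recombinase acts in Purkinje cells, the output neurons of the cerebellar cortex. The 2 control libraries came from littermates with Pcp2-Cre and 1 floxed copy. YY1 is a zinc finger transcription factor found in most cell types. Total counts were 18007663 and 17424860 in the controls and 20305705, 18872728 and 18895209 in the Yy1 cKO libraries. The labels call the samples mixed in sex without giving the sex of each. They do not say which animals or litters the replicates came from beyond their number, so p-values measure only the spread between these samples. Y-linked Ddx3y had 1175 counts in control 1 and 1471 in Yy1 cKO 3 and 0 in the other libraries, so each group held libraries with and without Y-linked transcripts. Xist had 12 and 6 counts in those 2 libraries and 29862 to 44119 in the others. These values argue against the 2 controls being 1 animal, and against Yy1 cKO 3 sharing an animal with Yy1 cKO 1 or 2. The spread between Yy1 cKO 1 and 2 may be technical. The first principal component, with 59.3% of the variance of log2 CPM, separated the groups, and Yy1 cKO 3 stood apart from all others on the second (18.5%).

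The comparison asks which transcripts of the cerebellum differ when Purkinje cells carry no intact Yy1, with Wnt10b and the development of dendrites named in the title of the series. Yy1 itself (ENSMUSG00000021264.12, chromosome 12, 108792973 to 108820148, GRCm38) stood at 74.6 and 73.7 CPM (TMM-scaled) in the controls and at 73.4, 81.7 and 75.8 CPM in the Yy1 cKO libraries. Its log2 fold change was 0.05 ± 0.065 (SE, adjusted p = 0.61), and -0.02 when libraries were scaled by their totals alone. Whole-tissue counts include the many cells without Cre and do not separate the deleted part of the gene, so this value checks the labels little.

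Cell cycle genes and several genes of immature neurons were far lower in the Yy1 cKO cerebella. Mki67, the proliferation marker, fell from 33.4 ± 6.0 CPM (SD, n = 2) to 1.36 ± 0.66 CPM (SD, n = 3), and Dcx, a microtubule protein of young neurons, fell from 299 ± 21.3 to 20.34 ± 0.46 CPM. Igfbpl1, with 646 and 575 counts in the controls, had 3, 1 and 2 counts in the Yy1 cKO libraries. Gains were smaller: Exph5, the gene with the smallest p among those that rose, went from 79.3 ± 4.4 to 249 ± 10.1 CPM, and Itpr1, the calcium release channel of Purkinje cells, from 1536 ± 17.2 to 2586 ± 292 CPM. Of 20388 genes tested, 2185 were higher and 2577 lower in Yy1 cKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were called for 236 higher and 874 lower genes, and at least 4-fold changes for 27 and 294. Scaling by library size alone gave 1432 higher and 3369 lower genes, so that 29.8% of calls were higher against 45.9% in the main test. Without control 1 or control 2 fewer genes were called, with no change of sign among the called genes still tested there. The groups overlapped in none of the 4762 called genes, so the lack of sign changes was nearly fixed beforehand.

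**Figure D1:**
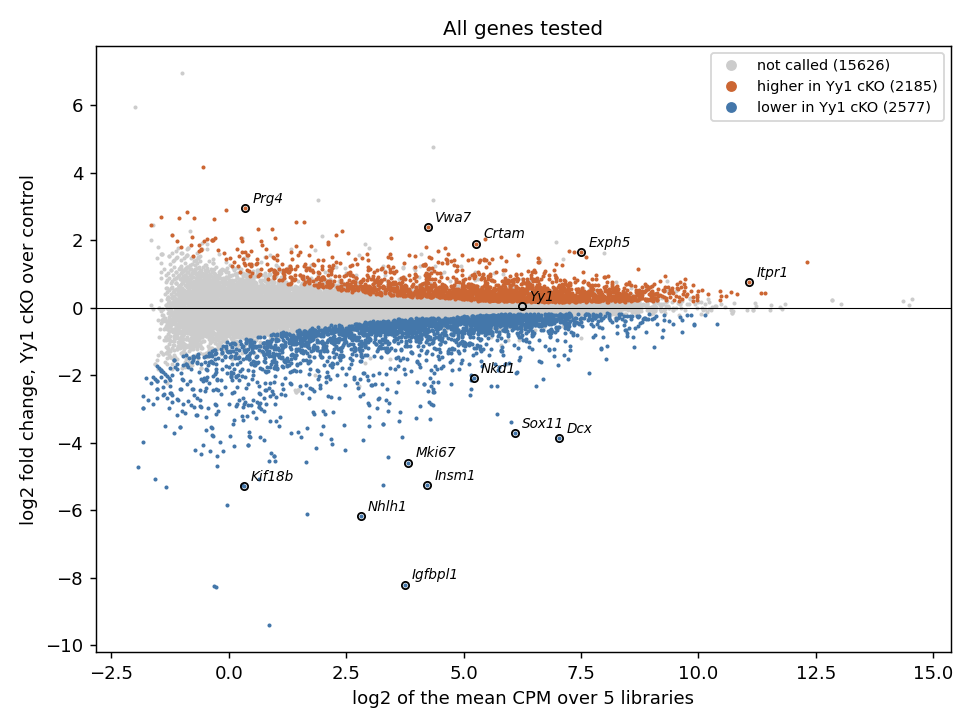
Each point is 1 of 20388 genes, with the log2 of its mean CPM over 5 libraries on the x axis and its log2 fold change (Yy1 cKO over control) on the y axis; orange points are the 2185 genes called higher, blue points the 2577 called lower and grey points those not called. The called genes that fell reach far larger changes than those that rose, with Igfbpl1 at -8.21, while Yy1 lies at 0.05.

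Among the genes that fell and had an established symbol and a mean of at least 1 CPM, those with the largest changes were mostly of a pair of kinds. Neuronal differentiation factors of granule cell precursors and their daughters included Nhlh1 (log2 fold change -6.19 ± 0.41, SE, adjusted p = 7.3e-05) and Insm1 (-5.27 ± 0.26). Division genes included Kif18b, a mitotic kinesin, with 71 and 40 counts in the controls and 3, 1 and 0 in Yy1 cKO, Pclaf, a partner of the replication clamp, with 88 and 50 against 3, 0 and 3, and Top2a, which fell by 4.43 ± 0.22. Hist1h3c, a histone H3 gene, fell by 5.27, but reads of near-identical histone copies make its own count uncertain. Mfap4, a matrix protein, was of neither kind (-4.22 ± 0.22). By smallest p the genes that fell were Dcx (-3.88 ± 0.066, adjusted p = 2.8e-09), Igfbpl1, Sox11 (-3.72 ± 0.089), Dpysl3 (-2.32 ± 0.058) and Marcksl1 (-2.12 ± 0.055), most of them known from neurons that are still migrating or growing axons.

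The genes that rose most were mostly rare transcripts. Prg4, lubricin, went from 0.24 to 1.96 CPM (log2 fold change 2.96 ± 0.44, adjusted p = 0.0012), Dmp1 from 0.68 to 4.03 CPM, Insrr, the insulin receptor-related receptor, from 0.44 to 2.26 CPM, Olfr287 from 0.55 to 2.77 CPM and Scx, a tendon transcription factor, from 1.56 to 7.05 CPM. Vwa7 (5.34 ± 0.49 to 27.9 ± 4.8 CPM) and Prr16 (3.75 ± 0.37 to 15.7 ± 2.4 CPM) were better measured. H2-K2, annotated as a pseudogene of the class I histocompatibility family, had a log2 fold change of 2.55, which is uncertain because its reads can be shared with its relatives. Serpinb1a and Mir300 both stood at 2.06, and their calls were lost without control 1 (adjusted p = 0.080 and 0.056), as was that of Serpinb1a without control 2 (adjusted p = 0.050). By smallest p the genes that rose were Exph5 (1.65 ± 0.064, adjusted p = 5.7e-07), Inpp5j, an inositol phosphatase (1.49 ± 0.060), Aifm3 (1.11 ± 0.055), Crtam (1.90 ± 0.097) and Itih3 (2.05 ± 0.10).

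Cell cycle genes fell almost as a block. Of 33 measured members of this list 29 fell (30 adjusted over the list alone) and 0 rose, with a median log2 fold change of -2.09 (camera adjusted p = 2.4e-35, adjusted p = 0.17 with an estimated correlation). Cenpf fell by 3.92 ± 0.19, Kif11 by 2.39 ± 0.19 and Ccna2, the S phase cyclin, by 2.63 ± 0.21. In the list of granule cell progenitor and Sonic hedgehog genes 14 of 23 fell (17 adjusted over the list alone) and 2 rose, with a median of -0.72 (camera adjusted p = 3.5e-30, adjusted p = 0.17 with an estimated correlation). Sox11 and Mfap4, above, belong to it, and Ccnd2 fell from 70.6 ± 6.8 to 11.7 ± 1.6 CPM and Barhl1 from 47.1 ± 0.23 to 13.2 ± 0.41 CPM. Atoh1, the factor that specifies these precursors, had 16 and 19 counts in the controls and 0, 1 and 0 in Yy1 cKO. The 2 members that rose were the receptors of Sonic hedgehog Ptch1 (0.34 ± 0.073) and Boc (0.31 ± 0.057), and Shh (0.14 ± 0.26, adjusted p = 0.76) and Gli1 (0.25 ± 0.26, adjusted p = 0.55) did not pass. Members named here and below because they went against their list, or as familiar members that did not pass, were chosen after their values were seen.

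Wnt10b (ENSMUSG00000022996.15, chromosome 15, 98770712 to 98778150, GRCm38), a secreted Wnt ligand, was close to the limit of detection. It had 46 and 6 counts in the controls and 3, 4 and 2 in Yy1 cKO, that is 2.47 and 0.33 against 0.15, 0.22 and 0.11 CPM. It did not pass the planned filter on low counts, so the planned test gave no value for it. Added back to that fit after this was seen, it had a log2 fold change of -3.10 ± 0.89 (adjusted p = 0.045). The call rested on control 1: without that library the change was -1.05 (adjusted p = 0.54), and it was also lost without Yy1 cKO 1, 2 or 3 (adjusted p = 0.15, 0.12 and 0.17). Among 11 other Wnt ligands measured, Wnt7a rose (52.9 ± 0.50 to 76.9 ± 6.0 CPM), and Wnt6 (1.76 ± 0.42) and Wnt5a (-0.60 ± 0.15) were called in the main test but not without control 1 (adjusted p = 0.086 and 0.18). As a list the ligands were not called (median 0.18, camera adjusted p = 0.41).

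Target genes of Wnt/beta-catenin signalling were lower as a list. Of 20 measured target genes 8 fell (8 adjusted over the list alone) and 0 rose, with a median of -0.39 (camera adjusted p = 6.3e-04, adjusted p = 0.29 with an estimated correlation). Nkd1, a feedback inhibitor of the pathway, fell from 68.8 ± 1.2 to 16.1 ± 1.0 CPM, Apcdd1 by 0.67 ± 0.075, Sp5 by 0.92 ± 0.15 and Lgr5 by 0.92 ± 0.16. Of 31 receptors and secreted regulators 10 fell and 4 rose (12 and 5 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.028, adjusted p = 0.57 with an estimated correlation). Sfrp1 fell by 1.95 ± 0.13 and Fzd2 by 1.80 ± 0.19, while the receptors Fzd1, Fzd4, Lgr4 and Ror1 rose by 0.30 to 0.44. This list was not called without control 2, Yy1 cKO 1 or Yy1 cKO 3 (adjusted p = 0.054, 0.068 and 0.060). The intracellular pathway genes, 3 higher and 7 lower of 37 (3 and 8 adjusted over the list alone), were not called by camera (median -0.11, adjusted p = 0.29) but were by fry (adjusted p = 0.0071), although Apc2 fell by 0.55 ± 0.054 and Apc by 0.49 ± 0.061. The fall in the Wnt lists stood beside that of cell cycle genes, and Sfrp1, Ccnd1, Lgr5 and Wif1 each belong to more than 1 of the lists described.

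**Figure D2:**
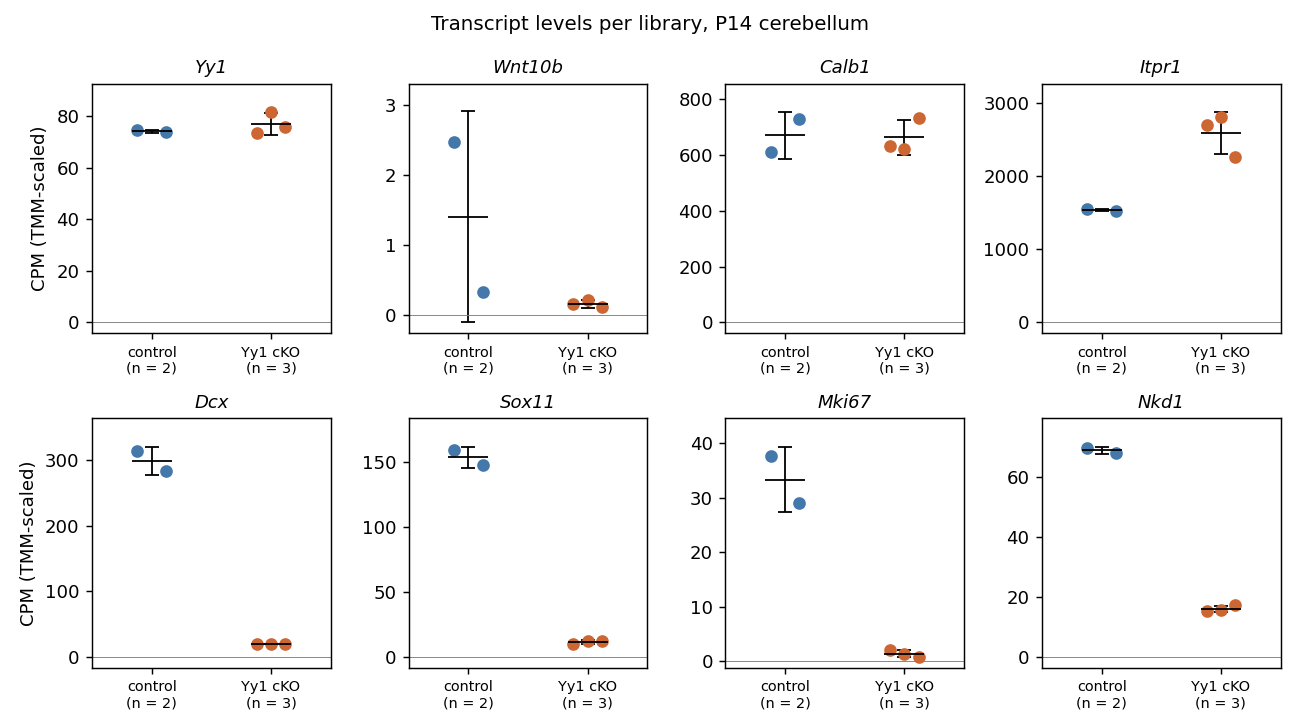
TMM-scaled CPM (y axis, linear) of 8 genes in each library, with controls in blue (n = 2) and Yy1 cKO in orange (n = 3); horizontal bars are means and whiskers 1 SD. Dcx, Sox11, Mki67 and Nkd1 lie lower in all 3 Yy1 cKO libraries and Itpr1 higher, Yy1 and Calb1 overlap, and the Wnt10b mean of the controls rests on 1 library at 2.47 CPM.

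More Purkinje cell markers rose than fell. Of 40 measured 10 rose and 3 fell (10 and 4 adjusted over the list alone), with a median of 0.19, and the Purkinje cell marker list was not called (camera adjusted p = 0.085). Calb1 stood at 670 ± 84.4 CPM in the controls and 663 ± 61.4 CPM in Yy1 cKO (log2 fold change -0.02 ± 0.099), and Pcp2, whose promoter drives the Cre, at 203 ± 62.7 and 234 ± 95.3 CPM. Itpr1 rose by 0.75 ± 0.097, Gad1, which makes GABA, by 0.60 ± 0.061 and Plcb4 by 0.49 ± 0.069. Cacna1g, Bcl11a and Nrgn fell. Without Yy1 cKO 3 the list was called (median 0.25, adjusted p = 0.0037). Genes of late Purkinje maturation were called higher, with 11 of 26 rising (11 adjusted over the list alone), 0 falling and a median of 0.28 (camera adjusted p = 1.5e-04, adjusted p = 0.57 with an estimated correlation), among them Atp2a3 (0.77 ± 0.063) and Kcna2 (0.71 ± 0.073).

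Genes of dendrite and spine development moved both ways and were called lower as a list. Of 51 measured 16 fell and 9 rose (17 and 9 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0038, adjusted p = 0.42 with an estimated correlation). The members with the smallest p were cytoskeletal genes that immature neurons of any kind express: Dcx, Marcks (591 ± 12.5 to 264 ± 7.1 CPM) and Stmn1 (86.0 ± 6.4 to 35.5 ± 0.18 CPM). Plxna4, a semaphorin receptor subunit, rose from 84.0 ± 3.3 to 154 ± 5.1 CPM. Genes of the parallel and climbing fibre synapses on Purkinje cells were called higher, with 15 of 31 rising and 3 falling (17 and 3 adjusted over the list alone), a median of 0.19, camera adjusted p = 0.0065 and adjusted p = 0.57 with an estimated correlation. Rims1, of the presynaptic active zone, rose by 0.64 ± 0.059 and Cbln3, a cerebellin of granule cells, by 0.70 ± 0.088. The 3 that fell were Slc17a6, a vesicular glutamate transporter (-1.64 ± 0.12), C1ql1 and Gnaq. Slc17a6 is also in the list of unipolar brush and nuclear neuron markers and C1ql1 in that of oligodendrocyte precursors, and the cell bodies of climbing fibres lie outside the cerebellum, so these values do not speak for climbing fibres. Of 39 inherited ataxia genes 15 rose and 5 fell (16 and 6 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.024, adjusted p = 0.39 with an estimated correlation). Kcna1 rose by 0.47 ± 0.058 and Ppp2r2b fell by 0.80 ± 0.087, and the list was not called without Yy1 cKO 1 (adjusted p = 0.052) or scaled by library size alone (adjusted p = 0.070).

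**Figure D3:**
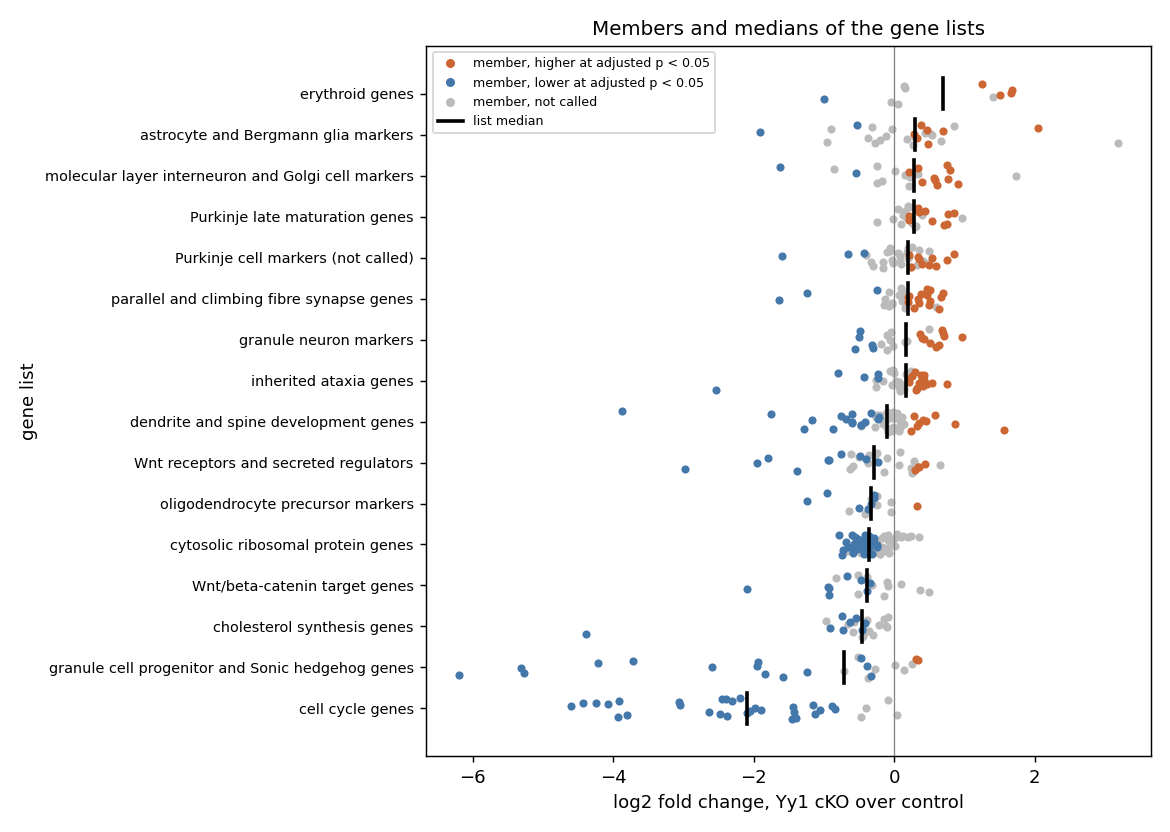
Log2 fold change (x axis, Yy1 cKO over control) of the measured members of 16 gene lists (y axis), with orange for members called higher, blue for members called lower, grey for those not called, and a black bar at each list's median. Medians run from -2.09 for cell cycle genes to 0.70 for erythroid genes, and the Purkinje cell marker list, at 0.19, was not called.

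Lists of granule neurons and of inhibitory interneurons were called higher. Granule neuron markers rose in 10 of 24 cases and fell in 5 (10 and 5 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.025, adjusted p = 0.57 with an estimated correlation). Car4 went from 55.3 ± 1.2 to 108 ± 12.1 CPM, Grin2c rose by 0.71 ± 0.079 and Gabrd, a subunit of tonic GABA receptors, by 0.60 ± 0.061, while Pax6, which is strongest in precursors and young granule cells, fell by 0.55 ± 0.051. The call was lost without control 1 (adjusted p = 0.051), without Yy1 cKO 2 (adjusted p = 0.057) and with scaling by library size alone (adjusted p = 0.067). Markers of molecular layer interneurons and Golgi cells rose in 10 of 22 cases and fell in 2 (11 and 2 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0044, adjusted p = 0.33 with an estimated correlation). Gad2 rose by 0.62 ± 0.058, Kit by 0.56 ± 0.060 and Prkcd by 0.79 ± 0.080, while Sst and Ptprk fell. Markers of unipolar brush cells and nuclear neurons, 3 higher and 4 lower of 14 (3 and 6 adjusted over the list alone), were not called by camera (median -0.18, adjusted p = 0.39) but were by fry (adjusted p = 0.020).

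Glial lists differed by type. Astrocyte and Bergmann glia markers rose in 7 of 26 cases and fell in 2 (9 and 6 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.016, adjusted p = 0.57 with an estimated correlation). Itih3 and S100b (0.70 ± 0.056) rose and Fabp7, a marker of young glia, and Aqp4 fell, and the list was not called without Yy1 cKO 3 (median 0.15, adjusted p = 0.088). Oligodendrocyte precursor markers fell in 7 of 15 cases and rose in 1, Ptprz1 (11 and 1 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.011, adjusted p = 0.44 with an estimated correlation). Gpr17, of committed precursors, fell from 108 ± 8.1 to 55.6 ± 6.3 CPM and C1ql1 by 1.24 ± 0.21. Markers of mature oligodendrocytes, 8 higher and 5 lower of 29 (10 and 7 adjusted over the list alone), were not called (median 0.10, camera adjusted p = 0.17) except without Yy1 cKO 2 (adjusted p = 0.033). Reactive glia genes, 0 higher and 5 lower of 21 (0 and 5 adjusted over the list alone), missed the threshold (median -0.41, camera adjusted p = 0.11), with Socs3 falling by 1.78 ± 0.16, and the reactive glia genes list was called without Yy1 cKO 3 (adjusted p = 0.0051). Microglia and macrophage markers changed in 1 of 25 cases, Fcrls (adjusted p = 0.48 for the list), and activated microglia genes rose in 6 and fell in 4 of 20 (adjusted p = 0.97 for the list).

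Of the housekeeping groups, cytosolic ribosomal protein genes and cholesterol synthesis genes were lower. Of 80 ribosomal protein genes 46 fell and 0 rose (48 and 2 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 1.4e-08, adjusted p = 0.42 with an estimated correlation), among them Rpl7 (-0.74 ± 0.059) and Rps4x (-0.79 ± 0.063). Many of these genes have processed pseudogenes that can share their reads, so single values are uncertain. Of 24 cholesterol synthesis genes 8 fell (13 adjusted over the list alone) and 0 rose, with a median of -0.45 (camera adjusted p = 3.6e-05, adjusted p = 0.57 with an estimated correlation). Mvd fell from 30.9 ± 1.6 to 16.4 ± 2.7 CPM. Nuclear oxidative phosphorylation genes (5 higher and 2 lower of 76) and mitochondrially encoded genes (0 of 13) were not called (medians 0.02 for both, camera adjusted p = 0.53 and 0.86), and both medians turned negative, at -0.05 and -0.06, with scaling by library size alone.

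Among lists of tissue other than the cerebellar cortex, erythroid genes were higher. Of 10 measured 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 0.015, adjusted p = 0.57 with an estimated correlation). Hba-a2 stood at 65.2 ± 5.7 CPM in the controls and 208 ± 46.7 CPM in Yy1 cKO, and its reads can be shared with those of Hba-a1. The list was not called without Yy1 cKO 3 (adjusted p = 0.34), and the Hba-a2 call was lost without control 1, control 2 or Yy1 cKO 3 (adjusted p = 0.081, 0.071 and 0.097). Blood transcripts thus differed between the groups beside the gene lists above. Markers of endothelial and mural cells (2 higher and 6 lower of 23, adjusted p = 0.22), meninges and fibroblasts (0 and 6 of 18, adjusted p = 0.25, and 0.0053 without control 1), choroid plexus (1 and 2 of 10, adjusted p = 0.93) and brainstem or midbrain neurons (1 and 1 of 6, adjusted p = 0.97) were not called by camera.

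The remaining fixed lists were not called by camera either. They were p53 and apoptosis genes (3 higher and 7 lower of 28, adjusted p = 0.19), unfolded protein and integrated stress response genes (1 and 6 of 25, adjusted p = 0.29), interferon response genes (2 and 0 of 20, adjusted p = 0.64), immediate early genes (2 and 1 of 20, adjusted p = 0.86), imprinted genes (9 and 8 of 33, adjusted p = 0.97), Yy1 and related factors (1 and 5 of 21, adjusted p = 0.996) and sex-linked genes (0 of 6, adjusted p = 0.99). The direction of the test went against the median of the activated microglia, interferon, immediate early, imprinted, choroid plexus and Yy1-related lists. In all, camera called 15 of 36 lists, 7 higher and 8 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.17 and 4 lists had an unadjusted p under 0.05. The fry test, which asks whether a list's genes move on balance in 1 direction, called 11, and its mixed form, for change in either direction, called 33. Of the lists that camera called, fry did not call those of late Purkinje maturation (adjusted p = 0.070), fibre synapses (0.054), granule neurons (0.081), astrocytes and Bergmann glia (0.081), cholesterol synthesis (0.081) and erythroid genes (0.10).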

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

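The GC content and length correction was chosen after the data were seen and all other alternatives before. No call changed sign under any of them. With 1 library left out this was nearly fixed beforehand, since the groups overlapped in none of the called genes. Of the 4762 called genes 4725 remained with DESeq2-style size factors, 4009 with library size alone, 3880 with the DESeq2 Wald test and 4274 with the GC content and length correction. Leaving out control 1 or control 2 kept 2094 and 2120, and leaving out Yy1 cKO 3 kept 4636. The number of genes higher in Yy1 cKO, 2185, was 1432 with library size alone, 771 against a minimum fold of 1.2, and 887 to 2990 with 1 library left out. The number of genes lower in Yy1 cKO, 2577, was 1349 against a minimum fold of 1.2 and 1267 to 3127 with 1 library left out. Adjusted p ran from 0.47 to 0.93 for Yy1, whose change lay between -0.02 and 0.09, negative only with library size alone. Over all other lists and named genes, 159 values were no longer called, 34 became called and 3351 kept their side of the threshold. An estimated correlation accounts for 15 of the lost list calls.

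For the Wnt10b log2 fold change adjusted p ran from 1.5e-07 without a filter to 0.54 without control 1. The call was lost with a mean CPM of at least 1 (-3.11, adjusted p = 0.051), limma-voom (-2.43, adjusted p = 0.17) and limma-trend on the deposited normalized values (-2.24, adjusted p = 0.065), and values ran from -3.90 to -1.05 with 1 library left out. The Purkinje cell marker list passed the threshold with no filter on low counts (median 0.20, adjusted p = 0.020) and with DESeq2 (0.20, adjusted p = 0.037), and its median was 0.085 to 0.25 with 1 library left out. Over its alternatives adjusted p ran from 0.0037 to 0.57. The causes were not tested. Wnt10b had 9 counts in all 3 Yy1 cKO libraries together and 52 in the 2 controls.

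The replicate numbers 1 and 2 occur in both groups, and whether they pair the samples could not be decided. Deviations of same-numbered libraries from their group means correlated at 0.037 and 0.013 across genes. With 2 controls the deviations are mirror images, so these values are not independent. Those of Yy1 cKO 1 and 2 share their distance from Yy1 cKO 3 (19.5 and 22.4 against -40.3 on the second principal component). The check was therefore weak. With the number as a replicate block 3486 genes were higher and 3575 lower, and the Purkinje cell marker list was called (median 0.27, adjusted p = 0.0069). Number 3 occurs only in Yy1 cKO, so in that fit Yy1 cKO 3 does not enter the comparison of the groups. The added calls therefore do not show an effect of pairing. Leaving out Yy1 cKO 3 also raised the counts, to 2990 higher and 3127 lower.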

Other observations

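The genes of the first 2 paragraphs, and the lists of angiogenic endothelium, fibroblast matrix, growth network and clock genes, were chosen after the leading results had been seen. Grin2b, the juvenile NMDA receptor subunit, fell from 220 ± 10.7 to 67.6 ± 6.7 CPM (log2 fold change -1.70 ± 0.081, adjusted p = 2.5e-06) while Grin2c rose and Grin2a did not pass (0.12 ± 0.054, adjusted p = 0.14). Of the GABA-A receptor subunits, Gabra2 (-0.60 ± 0.10) and Gabra3 (-0.50 ± 0.11) fell, and Gabra6 (0.43 ± 0.072) rose. The chloride transporters Slc12a5 (0.41 ± 0.071) and Slc12a2 (0.23 ± 0.060) both rose. The sodium channels Scn1a (0.75 ± 0.062) and Scn2a (0.62 ± 0.060) rose, and Dcc, a netrin receptor of growing axons, fell from 35.1 ± 0.12 to 9.74 ± 0.74 CPM. Of 65 clustered histone genes, whose messages are made in S phase, 50 fell and 0 rose, with a median of -1.94, and reads shared between copies leave single members uncertain.

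Of the lists of vessel and matrix genes, the planned ones for endothelial and mural cells (2 higher and 6 lower of 23, camera adjusted p = 0.22) and for meninges and fibroblasts (0 and 6 of 18, adjusted p = 0.25) were not called, while those written after the leading genes were seen were called lower, which is not independent evidence. In the fibroblast matrix list 10 of 18 fell and 0 rose, with a median of -0.91 (camera adjusted p = 5.5e-08, adjusted p = 0.18 with an estimated correlation). Fbn1, fibrillin 1, fell from 40.8 ± 1.7 to 12.4 ± 1.0 CPM and Eln, elastin, from 31.8 ± 1.3 to 12.2 ± 3.1 CPM. In the angiogenic endothelium list 8 of 14 fell and 1, Plvap, rose, with a median of -0.58 (camera adjusted p = 3.3e-04, adjusted p = 0.18 with an estimated correlation), and Aplnr, of sprouting vessels, fell by 2.37 ± 0.26. The growth network list, fetal genes that are turned off in many organs as growth slows, fell in 4 and rose in 1 of 13 cases, Peg3, and was not called by camera (median -0.43, adjusted p = 0.093) but was by fry (adjusted p = 0.041).

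The fall of cell cycle and granule cell progenitor transcripts was weighed against 4 explanations, with 3 tests written before their results were seen and that of maturity resting on lists chosen after the leading genes were. A smaller share of granule lineage tissue would lower all granule neuron markers about as much, but their median was 0.17 and the lowest member stood at -0.55, above the medians of both lists, so it is argued against as the whole cause, as is GC content or gene length bias, since correcting for both left the cell cycle median at -2.10 with 29 genes called. Fewer Shh transcripts could not be excluded, because the lower 95% limit of the Shh change was -0.45. A difference in maturity of the whole cerebellum predicted that at least 3 of 4 lists outside the granule and Purkinje lineages would move in the maturing direction, and 2 did, but these were the vessel and matrix lists chosen after leading genes were seen, so they decide nothing, and neither the planned oligodendrocyte list nor the growth network passed by camera. Slightly older or faster developing Yy1 cKO tissue therefore cannot be told apart from an effect of the genotype, since age was 1 nominal day for all samples.

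Nr1d1, a repressor of the circadian clock, rose from 64.0 ± 1.3 to 135 ± 5.2 CPM. A difference in clock phase between the groups may account for it, and directions for 7 other clock genes were written down before their values were seen. Phase predicted that all 7 would move that way, with more than 3 past the threshold. At most 3 moving that way would speak against it. Neither outcome occurred: 5 moved in the predicted direction, but only 3 of these, Nr1d2, Dbp and Tef, passed the threshold. Per2 and Npas2 went the other way. As a list these 7 were called higher (median 0.34, camera adjusted p = 0.034, fry adjusted p = 0.041), but not with an estimated correlation (adjusted p = 0.30). This call does not test phase, which predicted a fall of Arntl and Npas2, and the positive change of Npas2 adds to it. The labels give no time of collection, so a difference in clock phase stays open, as does an effect of the genotype.

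Of the long noncoding RNAs of the imprinted region beside Yy1, Mirg and Meg3 were higher, Mirg by 0.80 ± 0.067 and Meg3 by 0.48 ± 0.075, while Rian did not pass (0.27 ± 0.094, adjusted p = 0.075). Of 53 genes tested from Meg3 to Mirg (chromosome 12, 109541001 to 109749460, GRCm38), many of them microRNA precursors, 49 had a positive change, 10 rose and 0 fell. Several of the precursors lie within Rian or Mirg, so the 53 are not independent readings. The called share, 10 of 53, was below the 23.4% called among genes elsewhere. An effect of the floxed allele or its flanking region on neighbouring genes could reach this region, since the groups differ in copies of that allele. Of 31 other genes within 2 Mb of Yy1, 6 were called, 19.4% (exact 95% interval 7.45 to 37.5%) against 23.4% of genes elsewhere (one-sided Fisher's exact p = 0.765). A share at or below that of other genes had been written beforehand as the result that would speak against the effect, and it was met, but not by more than its interval; after the result was seen the criterion was tightened to ask for that, which leaves the effect open, and an effect of the genotype on the region was not tested.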
